A study of Mus musculus with 12 samples.

How the data were processed

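The series measured messenger RNA by paired-end sequencing in 12 cultures of osteoclasts, the bone-resorbing cells, grown from mouse bone marrow monocytes. Per the labels, the cells were wildtype (WT) or lacked Mincle (knockout, KO), were kept in M-CSF at 20 ng/ml and RANKL at 10 ng/ml, received osteocyte supernatant diluted 1:2 on day 1 for 24 hours, and were harvested on day 3. The supernatant came from viable osteocytes, the control, or from osteocytes made necrotic by serum starvation. Each of the 4 combinations of genotype and supernatant had 3 libraries, and the groups and replicate numbers were taken from the sample titles. Nothing in the labels says that the replicates came from separate animals or cultures, so the p-values measure only the spread between these samples, which may be technical.

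The authors deposited 1 table of raw counts per gene, whole numbers for 46983 Ensembl genes in 12 columns, without normalization, and every column name matched 1 sample title. Per the submitters' processing notes, the tools included CASAVA, HISAT2 2.0.5 and HTSeq 0.6.1 with the GRCm38 genome, and the libraries were made with a NEBNext Ultra kit per the labels' protocols. The trimming, the annotation release, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Reads from near-identical gene copies, such as immunoglobulin gene segments or retrocopies of ribosomal protein genes, and from genes that overlap on opposite strands, can therefore have been split or lost, and such genes are uncertain. Gene symbols, positions, transcript lengths and GC contents were taken from GENCODE release M21 on GRCm38, which matched 46488 of the identifiers and left 495 without a match. The total count per library ran from 16382366 to 49612055, and the next deepest library after WT viable replicate 3 held 25429661. A count of 0 in a library allows a level of up to 3 counts, which was between 0.06 and 0.183 counts-per-million (CPM) here, a limit that covers counting error only.

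Genes were kept with filterByExpr of edgeR 4.0.16 in R 4.3.3, which left 14153 genes and at least 99.92% of the counts of each library. Scaling used TMM factors, which lay between 0.971 and 1.02. One quasi-likelihood model with 4 group means and 8 residual degrees of freedom was fitted to all 12 libraries, so that the groups shared 1 estimate of the spread, and the biological coefficient of variation was 7.18%. Tests were two-sided with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The 5 contrasts were necrotic against viable supernatant in WT and in KO, the difference of these responses (KO minus WT), and KO against WT under each supernatant. Unless another test is named, an adjusted p comes from edgeR's quasi-likelihood test, the standard error (SE) of a log2 fold change is its size divided by the square root of the F statistic, and levels are TMM-scaled CPM given as mean ± SD with n = 3.

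A set of 36 gene lists with 603 members was fixed beforehand: osteoclast differentiation and resorption, negative regulators of osteoclast differentiation, ITAM and calcium signalling, C-type lectin neighbours of Mincle, inflammatory mediators, chemokines, NF-kB targets, interferon-stimulated genes, MHC class II presentation, alternative activation, oxidative phosphorylation encoded in the nucleus and in the mitochondrion, TCA cycle, mitochondrial biogenesis, glycolysis, hypoxia, cholesterol synthesis, LXR targets, lysosome, V-ATPase, podosome, integrated stress response, endoplasmic reticulum chaperones, heat shock, NRF2, cell cycle, p53 targets, immediate early genes and ribosomal proteins. Markers of macrophages, dendritic cells, neutrophils, mast cells and basophils, lymphoid cells, erythroid cells and platelets, and stromal and bone cells made up the rest. Lists were tested with camera of limma 3.58.1 on voom values with a preset correlation of 0.01, adjusted over the 36 lists of a contrast, and again with an estimated correlation and with fry. Members past the threshold were counted over all genes tested and adjusted over the list alone. Clec4e was left out of every list.

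The text names Clec4e, the 10 genes with the largest change in each direction among those past the threshold with at least 1 CPM, groups that do not overlap and no predicted-gene name, and up to 4 members of each list with the smallest p. Where no gene passed, the 3 with the smallest p in each direction are given. The groups, tests, lists, naming rule and most alternatives were chosen before the data were examined. The alternatives were median-ratio and upper-quartile factors, DESeq2 1.42.0, limma voom, no filter, a filter of 5 CPM in 3 libraries, fits with the compared groups alone, the replicate number as a block, an added 2-fold limit, and leaving out each library in turn. After the data were seen, 2 more were added: the deepest library thinned to the mean depth of the others, and a fit with offsets that remove the trend of each library with transcript length and GC content, modelled with natural splines on genes of at least 5 CPM. To compare a list with other genes of the same kind, 10000 random lists were drawn that were matched on transcript length, GC content and expression. For windows of 10 Mb on the chromosomes, the test against the best window of each random draw was added after the result was seen. It was first run with 10000 draws and then with 100000, since p varied with the seed, and p was under 0.05 in each run. The stricter limit of 0.01 used for it was set after that p was seen.

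The fit was tested on simulated counts with the real means, depths and dispersions and 50 changed genes of each fold size. It recovered 44.0% (WT response), 46.0% (KO response), 16.0% (difference of the responses), 42.0% (genotype, viable) and 46.0% (genotype, necrotic) of changes of 25%, the size nearest the median called fold. It recovered 80.0% of 1.5-fold and 94.0% of 2-fold changes in the WT response (13986 genes tested), 82.0% and 92.0% in the KO response (13990 genes), 80.0% and 84.0% for the difference of the responses (13984 genes), 80.0% and 98.0% for genotype under viable supernatant (14008 genes), and 66.0% and 96.0% under necrotic supernatant (14011 genes). The share of false calls was between 5.00% and 7.78%. The simulated genes were drawn independently and without the length and GC trends of the real libraries. These shares hold for that setting and may differ in the real data.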

Results

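RNA was sequenced from osteoclast cultures of WT mice and of mice without Mincle, a C-type lectin receptor of myeloid cells that is encoded by Clec4e and signals through an ITAM adaptor. The cultures had been exposed to the supernatant of viable or of necrotic osteocytes, and each of the 4 groups held 3 libraries. The comparisons address which genes of osteoclasts respond to the supernatant of necrotic osteocytes, and whether that response differs in cells without Mincle. Necrosis was induced by serum starvation, and no group received starved medium without cells. Products of dying cells therefore cannot be told apart from any difference in serum content or a loss of factors from viable osteocytes. The libraries held from 16382366 counts (KO viable 2) to 49612055 counts (WT viable 3), and the next deepest held 25429661 (KO necrotic 1). Lyz2, the gene of lysozyme, was the most abundant gene in all 12 libraries and took 1.5% to 1.8% of the counts. Within groups, log2 CPM values of replicates correlated across genes with r between 0.990 and 0.995, and every pair of replicates differed by more than sampling noise (chi-square per degree of freedom 3.28 to 23.3). In a principal component analysis of 1000 genes, the first component (34.3% of the variance) separated all 6 WT libraries (scores -19.5 to -5.65) from all 6 KO libraries (7.31 to 17.6).

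Clec4e itself (ENSMUSG00000030142, chromosome 6, 123281789 to 123289870, minus strand, GRCm38) was measured at 24.2 ± 1.71 CPM in WT viable and 25.1 ± 2.98 CPM in WT necrotic libraries, against 1.88 ± 0.479 CPM in KO viable and 1.94 ± 0.369 CPM in KO necrotic libraries (SD, n = 3 each). The KO level was lower by a log2 fold change of -3.66 (SE 0.15, adjusted p = 5.02e-10) under viable and -3.67 (SE 0.15, adjusted p = 4.10e-10) under necrotic supernatant, and no KO library (1.56 to 2.43 CPM) came near a WT library (21.9 to 27.8 CPM). Clec4e did not pass the test for a response to necrotic supernatant in WT (log2 fold change 0.04, SE 0.11, adjusted p = 0.853).

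**Figure D1:**
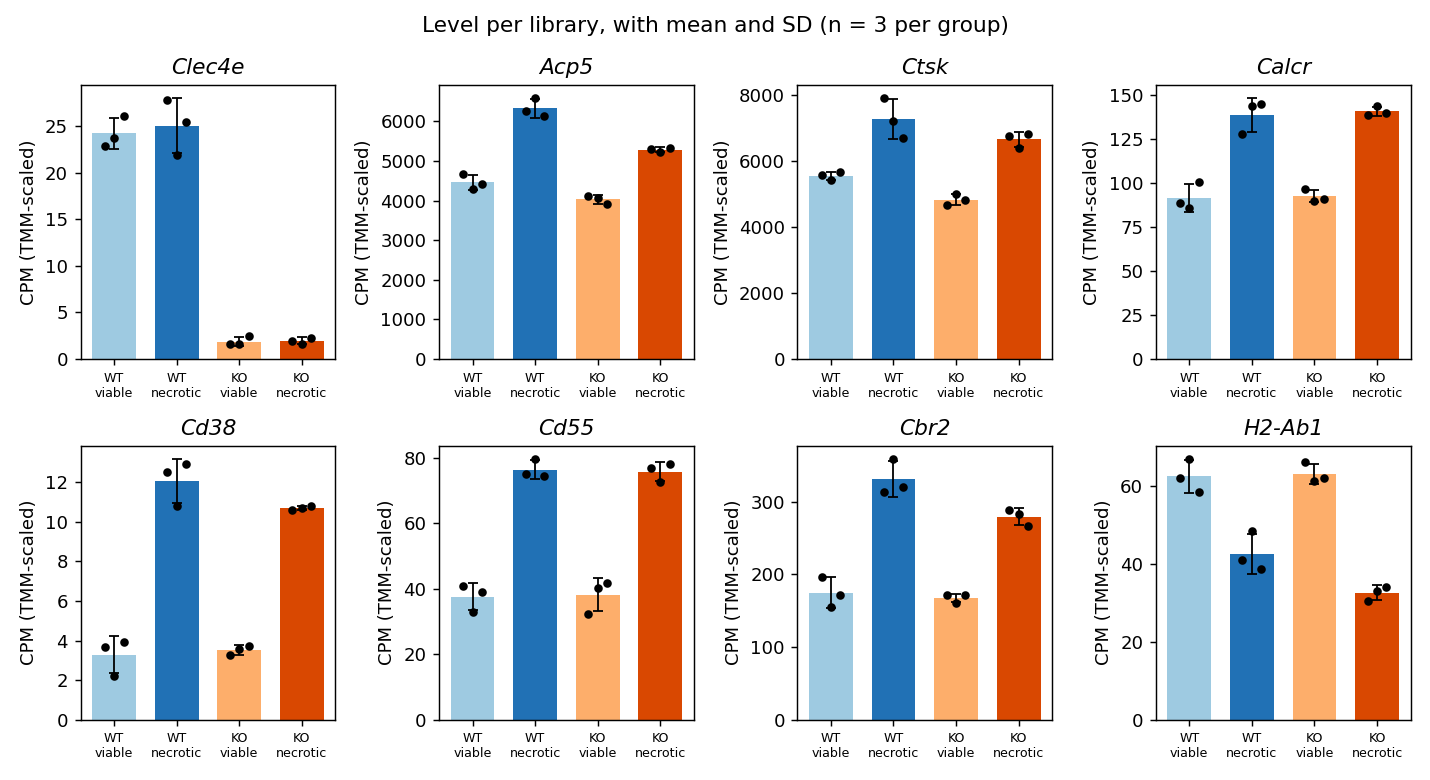
Levels of 8 genes in each of the 12 libraries, in TMM-scaled CPM on the vertical axes, by group on the horizontal axes. Bars are group means, error bars SD (n = 3) and points single libraries. Clec4e was at 21.9 to 27.8 CPM in WT and 1.56 to 2.43 CPM in KO libraries, while the other 7 genes show the response to necrotic supernatant in both genotypes.

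In WT cultures, necrotic supernatant raised 19 of 24 genes of osteoclast differentiation and bone resorption and lowered 11 of 24 interferon-stimulated and 5 of 9 MHC class II genes. The calls of the last 2 lists were lost with an estimated correlation (adjusted p = 0.295 and 0.178). Acp5, which encodes tartrate-resistant acid phosphatase, rose from 4460 ± 190 to 6330 ± 235 CPM (log2 fold change 0.51, SE 0.04, adjusted p = 1.25e-05). Calcr, the calcitonin receptor, rose from 91.9 ± 8.09 to 139 ± 9.34 CPM, and Ctsk, the collagen-degrading protease cathepsin K, from 5550 ± 116 to 7260 ± 603 CPM. Of 14153 genes tested, 681 rose and 637 fell (1318 in all), with a median absolute log2 fold change of 0.29 among them, and 54 of them changed at least 2-fold (11 up, 43 down).

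The largest rises in WT were those of Cd300ld3 (log2 fold change 2.24, SE 0.53, adjusted p = 0.0172), the acute-phase gene Saa3 (2.06, from 2.17 ± 1.04 to 10.0 ± 5.99 CPM) and Cd38, an NAD-consuming ectoenzyme (1.82, SE 0.15, adjusted p = 1.25e-05, from 3.29 ± 0.934 to 12.1 ± 1.14 CPM). Ankrd2 (1.19), Lims2 (1.02) and Cd55 (1.02), a regulator of complement, followed. Cbr2 rose from 175 ± 20.9 to 330 ± 24.9 CPM, and the alternative-activation genes Chil3 and Cd163, the haemoglobin scavenger receptor, rose by log2 fold changes of 0.91 and 0.82. The largest falls were those of Igha (-2.04), the dendritic cell lectin Cd209a (-1.49, from 3.08 ± 0.437 to 1.04 ± 0.264 CPM), the interferon-inducible GTPase Gbp4 (-1.39), Zbtb32 (-1.33) and Cacng8 (-1.29). The matrix genes Tnc (-1.25), Fbn1 (-1.20) and Col5a1 (-1.16), the growth factor gene Pgf (-1.20) and the noncoding RNA Kantr (-1.22) also fell.

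Of the 24 osteoclast genes, 19 rose, 0 fell and 5 did not pass, and 19 rose when adjusted over the list alone. The list had a median log2 fold change of 0.26 (camera adjusted p = 5.75e-20), and it was the only 1 of 36 lists whose call held with an estimated correlation (adjusted p = 0.0315, and 0.0649 in the fit with the length and GC trends removed, which ended the call). The cell fusion gene Ocstamp rose with it (0.46, adjusted p = 1.42e-04). Among the subunits of the V-ATPase, the proton pump that acidifies the resorption pit, 11 of 15 rose and 0 fell (13 and 0 adjusted over the list alone), among them Atp6v1e1 (0.35) and Atp6v1c1 (0.27). The median was 0.21 (camera adjusted p = 2.68e-10, and adjusted p = 0.0825 with an estimated correlation). Of 20 lysosome genes, 10 rose and 1 fell (13 and 1 adjusted over the list alone), with Hexa (0.27) up and the acid lipase Lipa down (-0.25). The camera call of the lysosome list (adjusted p = 1.95e-06) was not kept with an estimated correlation (adjusted p = 0.259).

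Some genes of mitochondrial respiration rose by small amounts in WT. Of 75 nuclear genes of oxidative phosphorylation, 27 rose and 0 fell (34 and 0 adjusted over the list alone), with a median of 0.15, for example Uqcrfs1 (0.28), Sdhd (0.25), Ndufv1 (0.24) and Atp5b (from 1740 ± 17.5 to 2020 ± 32.5 CPM). Of 15 TCA cycle genes, 7 rose and 0 fell (11 and 0 adjusted over the list alone), among them Mdh2 (0.28) and Fh1 (0.23). With an estimated correlation, the adjusted p was 0.259 for the first list and 0.172 for the second, against camera values of 6.91e-16 and 1.91e-08. None of 12 mitochondrially encoded genes and none of 18 glycolysis genes passed. Across 10143 genes, the WT log2 fold change was related to transcript length (Spearman rho -0.32), and random lists matched to the oxidative phosphorylation genes on length, GC content and expression had a median of 0.06.

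Interferon-stimulated genes fell in WT: 11 of 24 passed as lower and 0 as higher (21 and 0 adjusted over the list alone), with a median of -0.54, and Usp18 (-0.87), Oas3 (-0.73), Oas2 (-0.51) and Stat2 (-0.40) had the smallest p. Of 9 MHC class II genes, 5 fell and 0 rose, the same counts as adjusted over the list alone, with H2-Eb1 (-0.65), H2-Aa (-0.62), H2-Ab1 (-0.55) and their transcriptional activator Ciita (-0.51) among them. The camera calls (adjusted p = 4.26e-11 and 5.75e-05) were lost with an estimated correlation (adjusted p = 0.295 and 0.178). Cell cycle genes fell in 10 of 29 cases and rose in 0 (16 and 0 adjusted over the list alone), as for Uhrf1 (-0.44), Top2a (-0.23), Kif11 (-0.24) and Plk1 (-0.24), with adjusted p = 3.44e-07 by camera and adjusted p = 0.207 with an estimated correlation.

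Markers of other cell types moved with these groups in WT. Of 13 macrophage markers 7 rose and 1 fell (9 and 1 adjusted over the list alone): the complement genes C1qa (0.65) and C1qc (0.53) and Cd68 (0.28) rose, and Cx3cr1 fell (-0.77). Of 8 alternative-activation genes 5 rose and 0 fell (5 adjusted over the list alone), including Clec10a (0.39) and Il4ra (0.32). Dendritic cell markers fell in 2 of 8 cases (3 adjusted over the list alone), as for Cd209a and Itgax (-0.34), and lymphoid markers in 2 of 5 (2 adjusted over the list alone), as for Cd79a (-1.25). Stromal and bone markers fell in 3 of 10 cases (4 adjusted over the list alone), with Col1a2 from 29.2 ± 5.36 to 13.8 ± 3.01 CPM, Col3a1 (-1.03) and Alpl (-1.51). Camera called these 5 lists (adjusted p = 9.92e-06, 2.48e-06, 0.0360, 0.0205 and 5.80e-04 in the order given), but none with an estimated correlation (adjusted p = 0.172, 0.172, 0.178, 0.283 and 0.289). Cholesterol synthesis and uptake genes had a median of -0.14, with 1 of 21 lower, 0 higher and the same counts adjusted over the list alone (camera adjusted p = 0.0293, and adjusted p = 0.497 with an estimated correlation).

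The remaining lists passed camera in neither direction in WT. Among ITAM and calcium signalling genes 3 of 26 rose, the Fc receptor genes Fcgr3 (0.45) and Fcgr2b (0.27) and the adaptor gene Lcp2 (0.20), and 4 fell, including Prkcd (-0.29). Of the 8 C-type lectin neighbours of Mincle, Clec4a2 (0.25) and Clec4a1 (0.16) rose. Rbpj (-0.24) fell as the only 1 of 10 negative regulators, and 1 of 14 inflammatory mediators (Saa3) and 1 of 16 chemokines (Ccl24, 0.58) rose. Of 14 NF-kB targets 2 rose and 1 fell, of 13 neutrophil markers 2 rose (Elane 0.40, Mmp8 0.39) and 3 fell (among them Camp -0.35 and Ltf -0.32), and of 10 LXR targets 2 rose (Apoe 0.43, Nr1h3 0.39) and 1 fell (Fasn -0.37). In the stress lists, Hmox1 (0.41) and Osgin1 (0.27) rose among 15 NRF2 targets, Hspa1b (-0.83) and Hsph1 (-0.32) fell among 9 heat shock genes, Herpud1 (0.23) and Calr (0.16) rose among 11 chaperone genes, and Atf3 (-0.32) fell among 18 genes of the integrated stress response. Pdk1 (0.25, 1 of 12 hypoxia genes) and Gsn (0.18, 1 of 17 podosome genes) rose, and Mdm2 (-0.19, 1 of 11 p53 targets) and Klf4 (-0.42, 1 of 16 immediate early genes) fell. No member passed among 6 mast cell and basophil, 7 erythroid and platelet, 9 mitochondrial biogenesis and 22 ribosomal protein genes. The median, the mean and the test of a list differed in sign for 4 lists in WT (chemokines, NF-kB targets, glycolysis and podosome genes), and for 6, 5, 5 and 2 lists in the other contrasts, none of them called by camera.

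The WT count depended on single libraries: it was 2015 without WT viable 1, 385 without WT viable 2, 603 without WT viable 3 and 528 without WT necrotic 2. With the WT libraries alone in the fit it was 359.

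In KO cultures, the comparison asks for the same response in the absence of Mincle. Osteoclast genes rose again: Acp5 from 4030 ± 106 to 5290 ± 60.5 CPM (log2 fold change 0.39, SE 0.04, adjusted p = 1.04e-04). Ctsk rose from 4820 ± 171 to 6650 ± 225 CPM (0.46), Calcr from 92.7 ± 3.59 to 141 ± 2.67 CPM (0.61) and the sodium-proton antiporter gene Slc9b2 from 351 ± 11.5 to 474 ± 17.1 CPM (0.43). Of 9 MHC class II genes 6 fell, with H2-Ab1 from 63.1 ± 2.56 to 32.6 ± 1.90 CPM (-0.96, SE 0.08, adjusted p = 4.09e-05), and so did 17 of 24 interferon-stimulated genes. These list calls were lost with an estimated correlation (adjusted p = 0.0530 and 0.277). In all, 566 genes rose and 486 fell (1052 together), of which 36 changed at least 2-fold (13 up, 23 down).

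The largest rises in KO were those of Saa3 (log2 fold change 1.77, SE 0.47, adjusted p = 0.0341), Cd38 (1.60, from 3.52 ± 0.241 to 10.7 ± 0.121 CPM) and Cd55 (0.99, from 38.1 ± 5.02 to 75.8 ± 2.94 CPM). Tmod1 (0.82), Pacsin3 (0.81), Ankrd2 (0.78), Col15a1 (0.77), Chil3 (0.74), Gpm6b (0.74) and Cbr2 (0.74) came next. The largest falls were those of Cd209a (-1.62), Plxdc2 (-1.55), Pgf (-1.42), Ctnnd2 (-1.13), Zbtb32 (-1.11), Dmkn (-1.10) and Cacng8 (-1.10). The fractalkine receptor gene Cx3cr1 (-1.04), the interferon-induced gene Ifi44 (-1.03) and the plasmacytoid dendritic cell gene Siglech (-1.01) fell as well.

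Of 24 osteoclast genes 19 rose and 0 fell (21 and 0 adjusted over the list alone), with a median of 0.28 (camera adjusted p = 5.36e-24, and adjusted p = 0.0173 with an estimated correlation). Nuclear genes of oxidative phosphorylation rose in 49 of 75 cases and fell in 0 (71 and 0 adjusted over the list alone), with a median of 0.28, as for Cyc1 (0.33), Uqcrc2 (0.30) and Ndufa9 (0.28). TCA cycle genes rose in 10 of 15 cases (12 adjusted over the list alone), with Pdhb (0.33), Mdh2 (0.29), Dld (0.27) and Idh3b (0.25), and V-ATPase genes in 11 of 15 (11 adjusted over the list alone), with Atp6v1d (0.36) and Atp6v0e (0.30). Camera called these 3 lists (adjusted p = 2.13e-37, 1.54e-11 and 4.47e-10), and with an estimated correlation the values were adjusted p = 0.103, 0.0761 and 0.0623. Transcript length was related to the KO log2 fold change as well (rho -0.34), and lists matched to the oxidative phosphorylation genes had a median of 0.09.

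Interferon-stimulated genes fell in 17 of 24 cases (21 adjusted over the list alone), with a median of -0.60, as for Mx1 (-0.87), Oas3 (-0.86), Oas2 (-0.58) and Stat2 (-0.43). MHC class II genes fell in 6 of 9 cases (6 adjusted over the list alone), with a median of -0.82, among them H2-Aa (-0.93), H2-Eb1 (-0.85) and Cd74 (-0.83). With an estimated correlation the adjusted p was 0.277 and 0.0530 for these lists, against camera values of 1.88e-16 and 4.20e-11. With the length and GC trends removed, the MHC class II (adjusted p = 0.0143), TCA cycle (0.0254) and V-ATPase (0.0392) lists passed in KO with an estimated correlation, and oxidative phosphorylation did as well (0.0143). Neutrophil and precursor markers fell in 4 of 13 cases (4 adjusted over the list alone): Camp (-0.52), Ltf (-0.41), Ngp (-0.37) and Csf3r (-0.31). Immediate early genes fell in 3 of 16 cases (6 adjusted over the list alone, with 1 higher): Egr2 (-0.89), Klf4 (-0.52) and Klf2 (-0.29). The adjusted p was 0.307 and 0.374 with an estimated correlation for the last 2 lists, against camera values of 0.00182 and 6.27e-05.

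Of the macrophage markers 6 of 13 rose in KO, among them C1qa (0.46), C1qc (0.44) and Msr1 (0.23), and 1 fell (7 and 2 adjusted over the list alone), without a camera call (adjusted p = 0.0765). Alternative-activation genes had a median of 0.43 with 2 of 8 higher (5 adjusted over the list alone), Cd163 (0.70) and Chil3. Stromal and bone markers had a median of -0.56 with 0 of 10 past the threshold (2 lower adjusted over the list alone), and dendritic cell markers a median of -0.27 with 2 of 8 lower (3 adjusted over the list alone). Lymphoid markers had a median of -0.57 with 1 of 5 lower, Ighm (-0.65, 2 adjusted over the list alone). Camera called these 4 lists (adjusted p = 5.96e-05, 0.0124, 0.0111 and 0.0173), none of them with an estimated correlation (adjusted p = 0.189, 0.419, 0.106 and 0.307). Camera calls of the mitochondrially encoded genes (median 0.24, 1 of 12 higher, mt-Nd4 0.29), ribosomal proteins (0.08, 0 of 22), chaperones (0.09, 0 of 11), inflammatory mediators (-0.19, 1 higher and 1 lower of 14, with Nlrp3 at -0.19) and cell cycle genes (-0.06, 1 of 29 lower, Uhrf1 -0.25) were likewise lost (adjusted p = 0.335, 0.563, 0.307, 0.307 and 0.516 with an estimated correlation). With the length and GC trends removed, the mitochondrially encoded, ribosomal protein and chaperone medians were 0.10, 0.00 and 0.06. Camera then no longer called these lists (adjusted p = 0.0723, 0.836 and 0.0651), and it still called inflammatory mediators and cell cycle genes (adjusted p = 0.0199 and 0.0171).

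The KO count was between 383 and 647 when any of the 6 KO libraries was left out (607, 548 and 501 without KO viable 1, 2 and 3, and 484, 647 and 383 without KO necrotic 1, 2 and 3). With the KO libraries alone in the fit it was 1820.

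The WT and KO responses, which share no library, were alike for most genes that passed in either. Cd38, Cd55, Chil3, Cbr2, Ankrd2 and Saa3 rose in both, and Cd209a, Zbtb32, Cacng8 and Pgf fell in both. In total 289 genes rose in both, against 27 for independent lists, 215 fell in both, against 22, and 0 passed in opposite directions. Of the 1318 WT calls, 1252 had the same sign in KO, and of the 1052 KO calls, 1011 had the same sign in WT. Across all 14153 genes the log2 fold changes correlated with Pearson r = 0.40 and Spearman rho = 0.43, and across the 10152 genes of at least 5 CPM with r = 0.58. Genes are not independent replicates, so these describe the profiles and are not tests. Without WT necrotic 1 the r over all genes was 0.22.

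**Figure D2:**
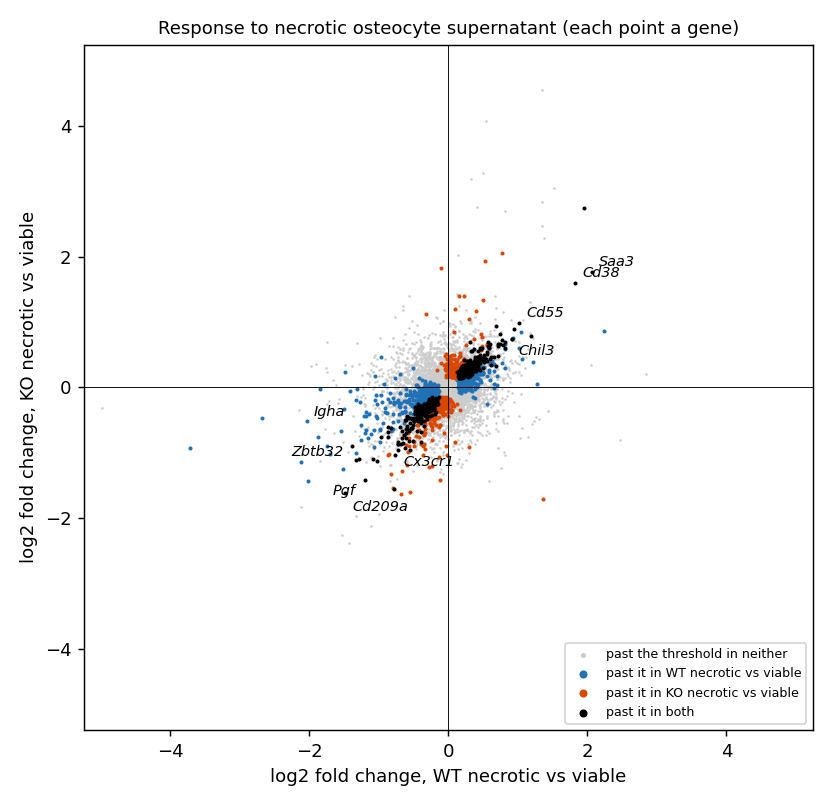
Log2 fold change of each tested gene between necrotic and viable supernatant in WT (horizontal axis) and KO (vertical axis). Black points passed the threshold in both genotypes, blue points in WT and not KO, orange points in KO and not WT, and grey points in neither; 289 genes rose and 215 fell in both.

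**Figure D3:**
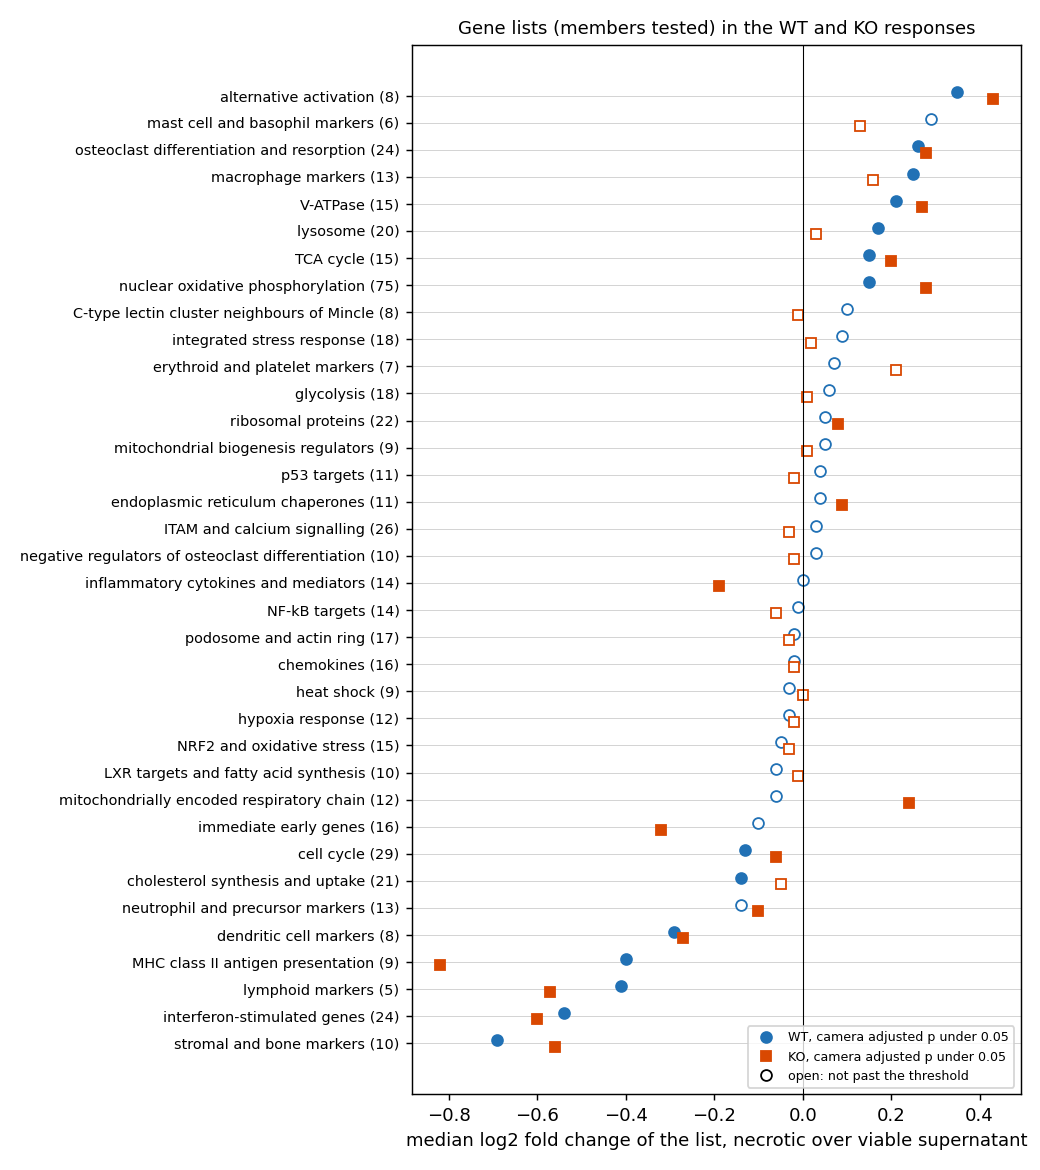
Median log2 fold change of each of the 36 gene lists between necrotic and viable supernatant, in WT (circles) and KO (squares), with the number of tested members in brackets. Filled symbols passed camera with the preset correlation, open symbols did not. Osteoclast genes had medians of 0.26 and 0.28, and MHC class II genes of -0.40 and -0.82.

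The difference between the responses was tested directly, since it bears on what differs between the KO and WT lines in their response. No gene passed: edgeR's quasi-likelihood test, DESeq2 and limma voom each gave 0 genes, with smallest adjusted p of 0.571, 0.391 and 0.518. In the edgeR test 1064 genes had an unadjusted p under 0.05 where chance gives 708. The genes with the smallest p and a larger value in KO were Snx7 (difference of log2 fold changes 0.44, SE 0.11), Zranb2 (0.34) and Timm23 (0.40). Those with a smaller value were Dynlt1c (-1.21, SE 0.28), Zfp414 (-0.51) and the inhibitory Fc receptor gene Fcgr2b (-0.29), all at adjusted p = 0.571. For the main osteoclast genes the difference was -0.11 (Acp5, SE 0.06, adjusted p = 0.682), 0.13 (Slc4a2) and 0.25 (Tm4sf19), and 0 of 24 passed, also when adjusted over the list alone. Within lists fixed beforehand, 5 of 12 mitochondrially encoded genes were higher, 2 of 9 MHC class II genes and 2 of 26 ITAM genes lower when adjusted over the list alone, and 0 over all genes. So adjusted, 1 of 8 C-type lectin neighbours of Mincle and 1 of 16 immediate early genes were lower and 1 of 29 cell cycle genes higher, and no member of the other 30 lists passed. H2-Ab1 (-0.40, SE 0.11) and Cd74 (-0.42, SE 0.12) fell further in KO by their point estimates, at adjusted p = 0.571. Camera called 10 of the 36 lists, among them MHC class II (median -0.21, adjusted p = 3.87e-05), macrophage markers (-0.11, adjusted p = 1.51e-04) and nuclear oxidative phosphorylation (0.12, adjusted p = 4.15e-06). None held with an estimated correlation (adjusted p = 0.351, 0.351 and 0.726 for these 3, and 0.329 at the smallest), and fry called 0. In the other contrasts fry called 13 lists in the WT response, 13 in the KO response and 8 by genotype under each supernatant. With an estimated correlation 1 list was called in each response and 0 by genotype.

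The median SE of this difference was 0.10 among genes above 5 CPM, and 8 of 50 simulated differences of 25% and 40 of 50 of 1.5-fold were recovered, where the median fold of the called responses was 1.22. A fit without the filter on low counts called 209 genes, 206 of them above the filter. In that fit 20 of 100 groupings of the supernatant labels, the real one included, gave as many (median of the others 42, highest 1176).

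Under viable supernatant, KO and WT cultures differed at Clec4e and at a group of genes with large differences. Wdfy1, an endosomal adaptor, was at 101 ± 5.21 CPM in WT and 22.7 ± 1.18 CPM in KO (log2 fold change -2.16, SE 0.06, adjusted p = 1.81e-12), and Cnbd2 at 33.8 ± 2.01 against 3.62 ± 0.265 CPM (-3.23, SE 0.10, adjusted p = 1.41e-11). Lrmda was higher in KO, at 6.41 ± 0.299 against 0.815 ± 0.258 CPM (2.84, SE 0.18, adjusted p = 1.14e-07). Of 14153 genes 406 were higher and 421 lower in KO (827 in all), and 85 differed at least 2-fold (33 higher, 52 lower). Upper-quartile scaling gave 303 higher and 619 lower.

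The kinase gene Camk2b was at 4.01 ± 0.475 CPM in WT viable and 0.0858 ± 0.0412 CPM in KO viable libraries, which is under the level that 3 counts give. Rab4a (-2.42), Nbea (-1.91), Aebp1 (-1.79), Loxl1 (-1.57), Col1a1 (-1.55) and Arg1 (-1.55) were lower in KO too. Higher in KO were the interferon-inducible gene Ifi208 (4.28 ± 0.868 against 0.171 ± 0.0577 CPM), Eps8l1 (5.47 ± 0.224 against 0.204 ± 0.141 CPM) and Mtus2 (1.75 ± 0.526 against 0.443 ± 0.192 CPM). Of the immunoglobulin genes, whose reads can be shared, Ighm did not pass (0.20, adjusted p = 0.269), and neither did the other 4 tested lymphoid markers. Higher in KO were Igkc (13.3 ± 0.436 against 4.17 ± 0.780 CPM, log2 fold change 1.63) and Ighg2b (12.4 ± 1.21 against 2.00 ± 0.708 CPM, 2.51). Jchain, which is not an immunoglobulin gene segment, was higher as well (2.64 ± 0.675 against 0.803 ± 0.136 CPM). The variable segments with a higher level in KO were Igkv10-96 (3.02 ± 1.06 against 0.161 ± 0.164 CPM), Igkv8-21 (2.18 ± 1.26 against 0.0195 ± 0.0337 CPM) and Ighv1-53 (1.87 ± 1.28 against 0.144 ± 0.152 CPM). Camk2b and Aebp1 lie within the first 10 Mb of chromosome 11, where 23 of 78 tested genes passed under both supernatants, against 2.11% of the genes elsewhere.

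Nuclear genes of oxidative phosphorylation were lower in KO viable cultures in 28 of 75 cases and higher in 0 (64 lower adjusted over the list alone), with a median of -0.22, for example Cox7a2 (-0.33), Ndufa9 (-0.28), Ndufb7 (-0.28) and Cyc1 (-0.22). Ribosomal protein genes were lower in 6 of 22 cases (13 adjusted over the list alone), as for Rpl18 (-0.30) and Rpl8 (-0.25). TCA cycle genes were lower in 6 of 15 cases (10 adjusted over the list alone), as for Ogdh (-0.23) and Pdhb (-0.22). Ogdh lies in the first 10 Mb of chromosome 11, where genotype calls cluster. Cell cycle genes were lower in 4 of 29 (10 lower and 1 higher adjusted over the list alone), as for Aurka (-0.26) and Mcm6 (-0.25). Camera called these 4 lists (adjusted p = 9.67e-25, 2.57e-09, 1.36e-07 and 8.38e-06), none of them with an estimated correlation (adjusted p = 0.287, 0.347, 0.276 and 0.347). The KO to WT log2 fold change rose with transcript length (rho 0.51 across 10143 genes), and lists matched on length, GC content and expression had a median of -0.10 for the oxidative phosphorylation and -0.10 for the ribosomal protein list.

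Stromal and bone markers were lower in KO viable cultures in 4 of 10 cases (6 adjusted over the list alone), with Col1a2 at 12.3 ± 5.49 against 29.2 ± 5.36 CPM, Col3a1 (-1.36) and Sparc (-1.21). Their call was not kept (camera adjusted p = 0.00207, and adjusted p = 0.412 with an estimated correlation). Of 24 osteoclast genes 3 were lower and 0 higher (4 lower adjusted over the list alone): Mmp9 (4910 ± 87.3 against 5730 ± 157 CPM, -0.22), Ctsk (-0.20) and Ckb (-0.20), with camera adjusted p = 0.0216 and adjusted p = 0.456 with an estimated correlation. Of 26 ITAM and calcium signalling genes 3 were higher (4 adjusted over the list alone), the lectin gene Clec4n (0.57), which neighbours Clec4e, Itpr2 (0.30) and Fcgr2b (0.29), with camera adjusted p = 0.00207 and adjusted p = 0.156 with an estimated correlation. Other lists with a camera call but none with an estimated correlation were NRF2 targets (1 of 15 higher, Gclm 0.22, adjusted p = 0.347), macrophage markers (1 of 13 higher, Mertk 0.29, adjusted p = 0.397) and chaperones (2 of 11 lower, Xbp1 -0.35 and Pdia6 -0.21, adjusted p = 0.276). So were podosome genes (2 of 17 higher, Cbl 0.39 and Myo9b 0.20, adjusted p = 0.433) and glycolysis genes (1 of 18 higher and 4 lower, Ldha -0.25, adjusted p = 0.416). The same held for heat shock genes (1 of 9 lower, Hspd1 -0.24, adjusted p = 0.287), V-ATPase genes (1 of 15 lower, adjusted p = 0.433), hypoxia genes (0 of 12, adjusted p = 0.465) and interferon-stimulated genes (0 of 24, median 0.17, adjusted p = 0.843). Xbp1, counted in the chaperone list, lies in the first 10 Mb of chromosome 11, where genotype calls cluster.

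Leaving out a library took the viable genotype count to 306 (WT viable 1), 315 (WT viable 2), 445 (KO viable 1), 227 (KO viable 2) or 228 (KO viable 3), and a fit of these 6 libraries alone gave 449. With the trends with length and GC content removed, a fit chosen after the data were seen, 563 genes passed, 421 of them among the 827, and the oxidative phosphorylation median was -0.09 with 6 members lower. In that fit 1 of 22 ribosomal protein genes (median -0.09) and 1 of 24 osteoclast genes were lower, and 3 of 12 mitochondrially encoded genes were higher (camera adjusted p = 0.00305, and adjusted p = 0.410 with an estimated correlation). Camera then no longer called the podosome (adjusted p = 0.175) and V-ATPase (0.190) lists.

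Under necrotic supernatant, Wdfy1, Cnbd2 and Lrmda again separated KO from WT, and Saa3, Acp5, Cd74 and H2-Ab1 were lower in KO as well. Wdfy1 was at 23.2 ± 0.888 CPM in KO and 115 ± 2.87 CPM in WT (log2 fold change -2.31, SE 0.06, adjusted p = 5.86e-13), Cnbd2 at 3.45 ± 0.220 against 30.7 ± 3.11 CPM (-3.15), and Lrmda at 7.45 ± 0.507 against 0.961 ± 0.145 CPM (2.93). Saa3 was at 3.13 ± 0.413 against 10.0 ± 5.99 CPM (-1.66, SE 0.35, adjusted p = 0.0136), and Acp5 at 5290 ± 60.5 against 6330 ± 235 CPM (-0.26, SE 0.04, adjusted p = 0.00306). In all 708 genes were higher and 442 lower in KO (1150 together), and 114 differed at least 2-fold (68 higher, 46 lower).

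Also lower in KO necrotic cultures were Camk2b (0.128 ± 0.116 against 4.16 ± 0.593 CPM), Nbea (-2.84), Rab4a (-1.91), Aebp1 (-1.83) and Efcab7 (-1.60). Rps27rt, a retrocopy of a ribosomal protein gene, passed too, but its SD in WT necrotic libraries (123 ± 120 CPM) was close to its mean. Higher were Ifi208 (3.21 ± 0.391 against 0.0901 ± 0.0675 CPM), Eps8l1 (4.42 ± 0.898 against 0.276 ± 0.255 CPM), and Mid1 (1.92 ± 0.297 against 0.164 ± 0.0889 CPM). Among immunoglobulin genes, whose reads may be shared, the higher ones were Igha (2.86), Igkv10-96 (2.11 ± 0.256 against 0.358 ± 0.443 CPM), Ighg2b (2.30), Ighg2c (1.91) and Igkc (10.8 ± 0.981 against 3.09 ± 0.828 CPM, 1.80). Jchain (1.91), which is not an immunoglobulin gene segment, was higher too.

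Neutrophil and precursor markers were lower in 6 of 13 cases (7 adjusted over the list alone), with the granule genes Mpo (-0.55), Elane (-0.53), Camp (-0.41) and S100a9 (-0.34). Glycolysis genes were lower in 8 of 18 cases (9 adjusted over the list alone), as for Pfkl (-0.37), Ldha (-0.26), Gpi1 (-0.25) and Eno1 (-0.25). Ribosomal protein genes were lower in 6 of 22 cases (12 adjusted over the list alone), nuclear oxidative phosphorylation genes in 9 of 75 (22 adjusted over the list alone), as for Atp5o (-0.29) and Cox4i1 (-0.26), and TCA cycle genes in 4 of 15 (6 adjusted over the list alone). Camera called these 5 lists (adjusted p = 7.19e-05, 3.73e-04, 3.99e-07, 2.34e-07 and 9.28e-05), but none with an estimated correlation (adjusted p = 0.464, 0.464, 0.464, 0.536 and 0.464). Transcript length was related to this contrast with rho 0.49 and GC content with rho -0.31.

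Mitochondrially encoded genes were higher in 3 of 12 cases (7 adjusted over the list alone), mt-Nd5 (0.53), mt-Nd3 (1.22) and mt-Nd4l (0.98), and MHC class II genes lower in 2 of 9 (4 adjusted over the list alone), Cd74 (-0.52) and H2-Ab1 (-0.39). Osteoclast genes were lower in 3 of 24 cases and higher in 1 (6 and 1 adjusted over the list alone), with Mmp9 (-0.25), Acp5 and Ocstamp (-0.20) lower and the lectin gene Siglec15 (0.41) higher. Inflammatory mediators were lower in 3 of 14 cases (5 adjusted over the list alone), Saa3, Lcn2 (-0.40) and Il1rn (-0.25). Camera called these 4 lists (adjusted p = 3.74e-05, 0.00974, 0.0480 and 0.0145) and none with an estimated correlation (adjusted p = 0.464, 0.464, 0.536 and 0.464). The other lists that camera alone called were NRF2 targets (3 of 15 higher, Gclm 0.36, Gclc 0.29 and Txnrd1 0.17, adjusted p = 0.536 with an estimated correlation), lysosome genes (2 of 20 higher and 3 lower, 0.577) and chaperones (1 of 11 lower, Xbp1 -0.29, 0.464). Xbp1 lies in the region of chromosome 11 where genotype calls cluster. Camera alone also called V-ATPase genes (1 of 15 lower, Atp6v0d1 -0.21, 0.464), stromal and bone markers (1 of 10 lower, Pdgfrb -0.83, 0.536) and hypoxia genes (1 of 12 lower, Ankrd37 -0.79, 0.536).

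Of the genes that differed between genotypes under 1 supernatant, 207 were higher and 122 lower in KO under both (329 in all, against 20 and 13 for independent lists), 0 passed in opposite directions, and 52 differed at least 2-fold under both. Both contrasts rose with transcript length (rho 0.51 and 0.49), which the values for independent lists leave out. Without immunoglobulin genes and genes without a position, 320 passed under both, and 188 did with the length and GC trends removed.

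**Figure D4:**
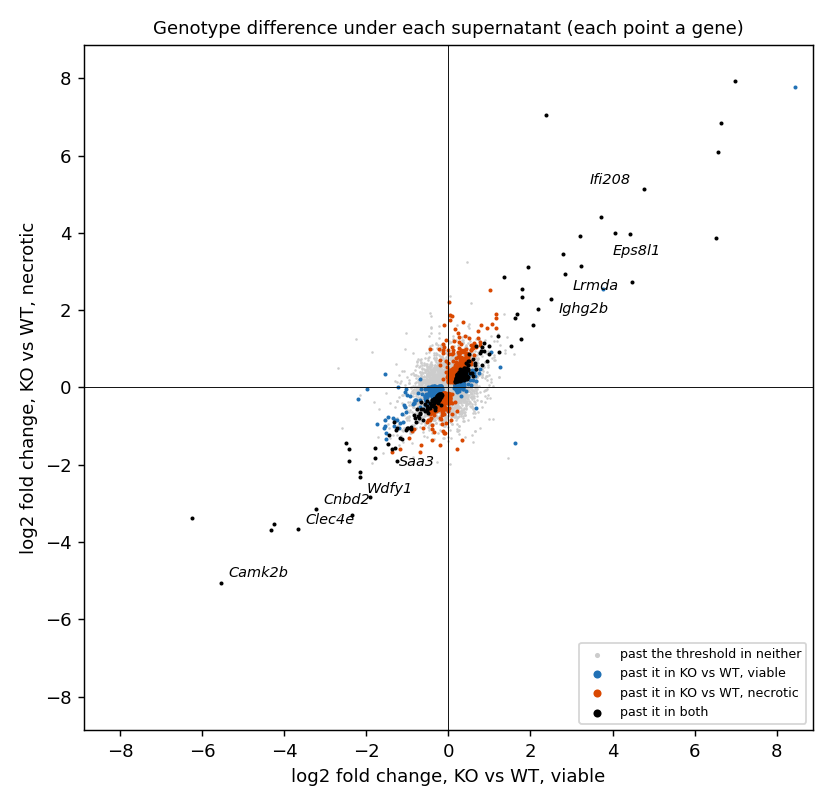
Log2 fold change of each tested gene between KO and WT under viable (horizontal axis) and necrotic (vertical axis) supernatant. Black points passed the threshold under both supernatants, blue points under viable and not necrotic, orange points under necrotic and not viable, and grey points under neither. Clec4e lies at -3.66 and -3.67. Fitted values beyond about 4 belong to genes with few counts in a group, such as Camk2b, and depend on the prior count.

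Leaving out a library took the necrotic genotype count to 250 (WT necrotic 2), 163 (KO necrotic 1), 341 (KO necrotic 2) or 659 (KO necrotic 3), and upper-quartile scaling gave 627 genes higher and 565 lower. With the trends with length and GC content removed, 597 genes passed (334 higher, 263 lower), 458 of them among the 1150, and the lower genes were 1 of 22 ribosomal protein, 2 of 75 oxidative phosphorylation (1 higher) and 2 of 18 glycolysis genes, with medians of -0.09, -0.05 and -0.06. In that fit 1 inflammatory mediator was lower. Camera then no longer called the osteoclast (adjusted p = 0.229), lysosome (0.382), V-ATPase (0.0748) and chaperone (0.0742) lists.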

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

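The tests of composition by macrophage markers and the fit with the length and GC trends removed were chosen only after the result was seen; the other tests in this part were fixed before.

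For 10 gene lists, camera on the difference between the KO and WT responses passed with the preset correlation, and this difference between the genotypes is why they are given here. The medians, KO minus WT on the log2 scale, were -0.06 for ITAM and calcium signalling (adjusted p = 0.00900, and 0.329 with an estimated correlation), -0.20 for inflammatory mediators (0.00897 and 0.359), -0.21 for MHC class II (3.87e-05 and 0.351), -0.11 for macrophage markers (1.51e-04 and 0.351) and -0.19 for neutrophil markers (0.00545 and 0.461). They were 0.12 for nuclear oxidative phosphorylation (4.15e-06 and 0.726), 0.23 for mitochondrially encoded genes (3.87e-05 and 0.461), -0.09 for lysosome genes (1.20e-04 and 0.461), 0.09 for cell cycle genes (0.00127 and 0.527) and -0.28 for immediate early genes (0.0120 and 0.773). No call held with an estimated correlation, and no gene passed. With the length and GC trends removed, the MHC class II median was -0.24 (camera adjusted p = 1.08e-04) and that of mitochondrially encoded genes 0.13 (camera adjusted p = 0.0762). The oxidative phosphorylation median was then 0.07 (camera adjusted p = 0.00101), and the immediate early call ended (median -0.28, camera adjusted p = 0.0762), while the other 6 lists stayed called by camera.

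Of 75 nuclear oxidative phosphorylation genes, 27 rose after necrotic supernatant in WT and 49 in KO, 28 were lower in KO under viable supernatant (6 with the trends removed), and all 3 contrasts followed transcript length. In 3 of 3 contrasts the list median lay outside the range of random lists matched on length, GC content and expression. The contrasts share libraries, and the random members were drawn independently, so this range leaves out the correlation among list members. It cannot decide whether a trend with length or GC content accounts for the whole pattern. The trends took a part. When they were removed, the medians moved from 0.15 to 0.14 (WT), from 0.28 to 0.18 (KO) and from -0.22 to -0.09 (genotype). RNA quality or library preparation may have set the length trend, and the files hold no measure of either. The deviation of a library from its group mean followed length differently between replicates. The rho was -0.53 in WT viable 1 against 0.33 and 0.38 in WT viable 2 and 3. It was 0.48 in WT necrotic 3 against -0.24 and -0.21 in WT necrotic 1 and 2, while KO viable libraries lay between -0.07 and 0.05. In KO necrotic 1, 2 and 3 it was 0.21, 0.05 and -0.24. An effect of the supernatant on mitochondria stays open as a hypothesis, and the list calls did not hold with an estimated correlation in the planned fit (with the trends removed, adjusted p = 0.0649 in WT and 0.0143 in KO).

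Of 24 osteoclast genes 19 rose after necrotic supernatant in each genotype. The WT median lay 0.23 above that of matched random lists, whose members were also drawn independently. With the trends removed the medians were 0.26 in WT and 0.30 in KO (adjusted p = 0.0649, no longer past the threshold, and 0.0143 with an estimated correlation). Removing the modelled trends thus did not lower the medians, while the WT list call was not kept. A larger share of osteoclasts that dilutes every other cell type alike stays open in both genotypes. Of 13 macrophage markers 7 rose and 1 fell in WT (list adjusted p = 0.172 with an estimated correlation). In KO 6 rose and 1 fell, and camera did not call the list (adjusted p = 0.0765). The MHC class II and dendritic cell lists had negative medians in both genotypes. The macrophage markers were not shown to be absent from osteoclasts, so their rise cannot decide this. Other shifts in composition and a higher expression per cell stay open.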

How the results depend on the processing

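The fits with the length and GC trends removed and with the deepest library thinned were chosen after the data were seen. No gene or list past the threshold in the main or the alternative fit reversed, and signs were not compared where neither passed. Among named genes, 12573 comparisons with an alternative kept their status, past the threshold in both fits or in neither. In 752 the call was lost and in 447 it was gained, and among lists the counts were 1989, 164 and 43. Clec4e stayed between -3.92 and -3.55 and was always called, and the odds ratio of calls near it was 1.43 within 5 Mb and 1.22 within 20 Mb. The WT response count of 1318 became 359 with the compared groups alone, 54 with an added 2-fold limit and 385 to 2015 without 1 library. The KO response count of 1052 became 1820, 36 and 383 to 647 under the same settings. The difference of responses stayed at 0 except without the filter (209). There 20 of 100 groupings of the supernatant labels, the real one included, gave as many, in a test run after the 209 was seen. Some regroupings keep a part of the response, so this share is not a pure chance share. The viable genotype count of 827 became 1618 without the filter, 449 with the compared groups alone, 85 with the 2-fold limit and 227 to 894 without 1 library. The necrotic genotype count of 1150 became 1857 without the filter, 597 with the trends removed, 114 with the 2-fold limit and 163 to 1380 without 1 library. The correlation of the responses was 0.73 among genes called in either, 0.58 above 5 CPM and 0.22 to 0.42 without 1 library. Fewer libraries or groups change the estimate of the spread, and the 2-fold limit removes genes by construction. With the compared groups alone the WT count fell and the KO count rose, so the order of the 2 counts reversed. Both counts thus depend on the shared estimate of the spread, and 1318 against 1052 does not rank the 2 responses. Otherwise the cause was not tested. DESeq2 gave 1477, 1212, 0, 1149 and 1350 genes and voom 1390, 1072, 0, 891 and 1101 in the order of the contrasts, and thinning 1248, 1031, 0, 798 and 1176. With the replicate number as a replicate block the counts were 1231, 947, 0, 744 and 1154, and with a replicate block within genotype 1494, 1274 and 0 for the first 3 contrasts. Libraries with the same number had r between -0.62 and 0.26 over 2000 genes, so the numbers gave no uniform sign of pairs. Between KO viable and KO necrotic libraries the same-number values (0.08, 0.17 and 0.26) lay above all different-number values (-0.35 to 0.04). A weak pairing in KO is therefore possible. Some libraries with different numbers went together, as WT necrotic 1 and KO necrotic 2 (r = 0.64), and others went apart.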

Other observations

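The tests on chromosome 11, the merged neighbour pairs, the sterol genes and the splits with the trends removed were chosen only after the result was seen. The tests of splits, of the region near Clec4e and of neighbour pairs were fixed before. The glucocorticoid list was added after Tsc22d3, Fkbp5 and Cd163 had been seen and left these out. Its test was fixed before the values of the other targets were examined.

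At the start of chromosome 11, 23 of 78 tested genes (29.5%) differed between KO and WT under both supernatants, 6 higher and 17 lower, against 2.11% elsewhere (Fisher's exact p = 7.39e-20). They included 8430429K09Rik (log2 fold change -4.25 under viable and -3.53 under necrotic supernatant), Inpp5j (-2.34 and -3.29), Selenom (-0.76 and -0.55), Polm (-0.69 and -0.66), the adaptor gene Ap1b1 (-0.49 and -0.65), the ribosome assembly gene Pes1 (-0.45 and -0.54), Limk2 (-0.36 and -0.30), Xbp1 (-0.35 and -0.29) and Ogdh (-0.23 and -0.32). Nudcd3 (0.43 and 0.43), Patz1 (0.36 and 0.40) and the vitamin B12 carrier gene Tcn2 (0.45 and 0.22) were higher in KO. Among windows of 5 Mb across the genome, the first 2 of chromosome 11 had adjusted p = 5.11e-11 and 3.41e-05, and the next, on chromosome 2, had 0.0701.

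Genes that differed by genotype may lie in segments of another strain's genome carried with the KO line, a hypothesis. The 43 genes with at least 2-fold differences under both supernatants, without 9 immunoglobulin genes, formed 13 neighbour pairs within 5 Mb, against a median of 5 in random draws (permutation p = 5.00e-04, 10000 draws), and 20 pairs formed with the immunoglobulin genes. After genes within 100 kb were merged, 6 pairs were left (random median 4, permutation p = 0.279), so reads shared between adjacent genes cannot be told apart from segments genome-wide. On chromosome 11, 7 merged loci were left (random median 2). With each random draw given its best of 278 windows the permutation p was 0.0460, and the window width was also chosen after the result was seen. Shared reads therefore stay open there as a source of calls within a locus. They cannot join the 7 merged loci to each other, since these lie more than 100 kb apart. The length or GC trend does not account for the cluster, with 24 genes called after its removal (30.8% against 1.17% elsewhere). Near Clec4e the odds ratio of a call within 10 Mb was 1.35 (confidence interval 0.753 to 2.27, Fisher's exact p = 0.234, 16 of 208 genes), which neither shows nor excludes flanking sequence of another strain.

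Necrotic supernatant may carry more glucocorticoid activity, a hypothesis raised by Tsc22d3 (0.68), Fkbp5 (0.60) and Cd163 in WT: of 15 other tested targets 26.7% rose in WT (Per1 0.37, Klf9 0.40, Mt1 0.25 and Mt2 0.52) and 20.0% in KO, while Sgk1 fell (-0.35), which left it undecided. Less serum lipid in the supernatant of starved cells, which could raise sterol synthesis genes, stays undecided: their median was -0.14 in WT and -0.05 in KO with members in both directions, 0 of 21 rose, and neither list passed with an estimated correlation (adjusted p = 0.497 and 0.714).

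With 10 splits of 6 libraries, the smallest share of splits that can give as many genes, 1 of 10, lies above 0.05. The real and the highest other counts were 1318 and 458 (WT response), 1052 and 4 (KO response), 827 and 0 (viable genotype) and 1150 and 1 (necrotic genotype). The WT split with 458 genes gave 6 after the length and GC trends were removed. For the difference of responses the real count was 0. All 100 of 100 groupings, the real one included, then gave as many by construction, so this share says nothing about chance. The highest gave 38. Nnt, of which the C57BL/6J strain is known to carry a deletion, was lower in KO (-0.92 under viable and -1.08 under necrotic supernatant) and was looked up after its value was seen.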
